A study of Homo sapiens with 18 samples.

How the data were processed

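Messenger RNA was sequenced from 18 libraries of cultured cancer-associated fibroblasts (CAFs), the fibroblasts of the tumour stroma. A lung adenocarcinoma CAF line and a pancreatic adenocarcinoma (PDAC) CAF line, both commercial, were each kept for 48 h in 1 or 3 µM of GNE-7883, an inhibitor of TEAD, or in a matching amount of the solvent DMSO, per the labels' protocols. TEAD proteins are the DNA-binding factors through which YAP and TAZ, the effectors of the Hippo pathway, act on transcription. The 2 lines and 3 treatments made 6 groups of 3 libraries. Polyadenylated RNA was made into stranded libraries and read single-end, per the labels' protocols. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Each tumour type was represented by 1 line, so line, donor and tumour type cannot be told apart.

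The deposited raw table holds whole-number counts for 58302 rows, of which 24297 had no read in any library. The submitters' processing notes name fastp 0.23.4, edgeR, limma and the genome build GRCh38, without role or order. The aligner, the counting tool, the annotation and the strand setting of the counting are not given in the sources used here. The authors also deposited a table named as CPM (counts scaled by library size), here treated as a signal scaled per library, because its columns sum to between 918826 and 1114213. Dividing each of its values by the smallest positive value of its column gave whole numbers (within 1e-04) for 100% of values, and each of its 18072 rows matched exactly 1 row of the count table. Those 18072 rows were also the rows that edgeR's filterByExpr kept from the count table. The scaling factors read from the scaled table differed from edgeR's TMM factors by at most 0.000481. The scaled table was used for these checks and for an added repeat of the tests on its recovered reads.

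Neither table pairs its rows with a gene name or identifier, and row order was not used to assign names. Rows are called genes below, taking each to be 1 gene. The gene lists fixed before the data were examined (Hippo, CAF, matrix, cell cycle, interferon, cell type marker and other lists) could therefore not be applied, and none of the planned list tests was run. The planned rule for named genes left out rows without a symbol and could not be followed as written. Only its part on genes changed the same way in both lines at 3 µM was kept: the largest in each direction by the smaller of the 2 absolute log2 fold changes, with a mean CPM of at least 5 in the higher group of each line. That choice, the limit to 2 genes per direction and the use of row numbers were made after the data were seen. Checks of gene length, GC content, mitochondrial share, other cell types, overlapping genes and reads shared by paralogs need gene identities and were not possible. The planned removal of sex-linked genes was not possible either, so such genes are among those counted, and no row is singled out from the baseline comparison of the lines.

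Counts were tested with edgeR 4.0.16 in R 4.3.3. Rows passed filterByExpr with a minimum count of 10 and a minimum total of 15, and the rows kept held at least 99.95% of the reads of every library. Library sizes were scaled by TMM. A single quasi-likelihood model over the 18 libraries with 6 group means had 12 residual degrees of freedom. Contrasts were tested with the two-sided quasi-likelihood F-test, and p-values were adjusted by the Benjamini-Hochberg method over the 18072 genes, with 0.05 as the threshold. The contrasts were each dose against DMSO in each line, 3 against 1 µM in each line, the difference between the lines in the response to each dose, and PDAC against lung CAFs in DMSO. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values in the text were computed from the raw counts with the TMM-scaled library size. A response score was computed per library over the genes called at 3 µM in the other line: the mean log2 CPM (prior count of 2) relative to the mean of the DMSO libraries, signed by the direction in the other line. The fold changes behind this choice of genes used none of the libraries scored, but the dispersions did, so the score was repeated with genes called in the other line fitted alone. Both scores were chosen after the data were seen.

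The alternatives fixed before the data were examined were relative log expression (RLE) and upper-quartile scaling, no filter, a filter at 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), robust quasi-dispersions, each line fitted alone, the replicate number as a block, a log2 fold change of at least 1, and leaving out each library. Chosen after seeing the data were the tests on the recovered reads, thinning to equal depth, leaving out both PDAC replicate 2 at 3 µM and lung DMSO replicate 3, and a covariate for the axis along which libraries differed within groups. No pair of replicates agreed within sampling noise: over genes with at least 20 reads in the pair, the chi-square per degree of freedom was 3.07 or more in each pair.

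Depth was 31876059 to 46530161 counts per library. The tests were tried on counts from 1 simulation per comparison, drawn with each line's mean DMSO levels and the dispersions and depths of these libraries. In each, 50 genes of at least 1 CPM were changed by each of 4 known amounts. Genes were drawn independently, with 1 dispersion per gene for all groups. The simulations thus lacked the wider spread of the real PDAC libraries at 3 µM and any axis within groups. They also changed fewer genes than were called in the data, so the shares hold for that setting only. For lung CAFs at 3 µM against DMSO over 17682 genes, edgeR recovered 14% of genes changed 1.25-fold, 66% of those changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 4-fold, and 4.20% of its calls were false. For PDAC CAFs at 3 µM against DMSO over 17674 genes, the shares were 20%, 64%, 90% and 98%, with 4.90% false calls. The share of false calls was 10.5% and 12.3% for DESeq2, above the threshold of 0.05, and 5.67% and 5.59% for limma-voom in the lung and PDAC simulations.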

Results

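Gene expression was measured in 18 RNA-seq libraries of a lung adenocarcinoma CAF line and a PDAC CAF line. Each line had 3 libraries in DMSO, 3 at 1 µM and 3 at 3 µM of the TEAD inhibitor GNE-7883. Total counts ranged from 31876059 to 46530161 per library, and between 13334 and 13580 rows of the count table reached 1 CPM. The 10 most abundant rows took 10.9% to 18.1% of the reads. Of the 58302 rows, 18072 were abundant enough to test. The files do not pair rows with gene names, so genes are described by number, direction, size and abundance, and 4 of them by row number. The first principal component of log2 CPM held 82.3% of the variance and separated the lines. Within the lung line alone, the first component held 40.5% of the variance, and all 6 treated libraries lay on the other side of 0 from the 3 DMSO libraries. The same held within the PDAC line for a first component with 31.0% of the variance.

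The first question was which genes the inhibitor changed in lung CAFs. At 3 µM, 2285 genes rose and 2179 fell against DMSO, together 24.7% of the genes tested (edgeR quasi-likelihood test, adjusted p under 0.05, n = 3 per group). The median absolute change of these genes was 1.40-fold, and 425 rose and 368 fell by at least 2-fold. At 1 µM, 1812 genes rose and 1637 fell, with a median absolute change of 1.39-fold, and 317 rose and 264 fell by at least 2-fold. Among the 100 genes with the highest CPM, 30 rose and 28 fell at 3 µM. The genes called higher at 3 µM took 19.5% ± 0.689 of the reads in DMSO and 27.7% ± 0.665 at 3 µM (SD, n = 3). Those called lower took 27.0% ± 0.475 in DMSO and 19.4% ± 0.623 at 3 µM. These genes were chosen on the same libraries, so the shares describe the calls and do not test them. Genes called at 3 µM made up 8.96% of the 4518 least abundant genes and 38.0% of the 4518 most abundant. Of the 793 genes that changed at least 2-fold, 343 were among the 4518 least abundant and 86 among the 4518 most abundant. Smaller changes can pass the test at higher counts, so these shares do not show that abundant genes responded more often.

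The same question was asked of PDAC CAFs. At 3 µM, 1549 genes rose and 1507 fell, together 16.9% of the genes tested, with a median absolute change of 1.38-fold (edgeR, n = 3 per group). The near-even split of directions was not fixed: 59.6% of the calls were rises with upper-quartile scaling, 45.1% with the axis covariate, and 45.0% without replicate 3 at 3 µM. Of the 3056 genes, 286 rose and 228 fell by at least 2-fold. At 1 µM, 1011 genes rose and 788 fell, with a median absolute change of 1.42-fold, and 208 rose and 138 fell by at least 2-fold. Among the 100 most abundant genes, 32 rose and 9 fell at 3 µM. The genes called higher at 3 µM took 17.0% ± 0.336 of the reads in DMSO and 22.6% ± 0.1995 at 3 µM, and those called lower took 12.5% ± 0.343 and 8.76% ± 0.348 (SD, n = 3). Replicate 2 at 3 µM lay apart. Of 10170 genes with a mean of at least 5 CPM, 1254 were at least 1.5-fold off the mean of the other 2 libraries. In replicate 3 at 3 µM it was 706 genes, but the mean there included replicate 2. Every other library had 188 or fewer. The chi-square per degree of freedom was 19.6 between replicates 1 and 3 at 3 µM. It was 59.2 and 120.7 for replicates 1 and 3 against replicate 2, while pairs of PDAC DMSO libraries reached 25.4. Without replicate 2 at 3 µM alone, the PDAC count at 3 µM was 3055, and 2394 of the 3056 genes were called again in the same direction. With lung DMSO replicate 3 left out as well, a choice made after seeing the data, the PDAC count at 3 µM was 3491. The PDAC count at 1 µM then rose from 1799 to 3088. Fitted without the lung libraries, the PDAC counts were 1986 at 3 µM and 1102 at 1 µM, while the lung line fitted alone gave 5798 and 4756.

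**Figure D1:**
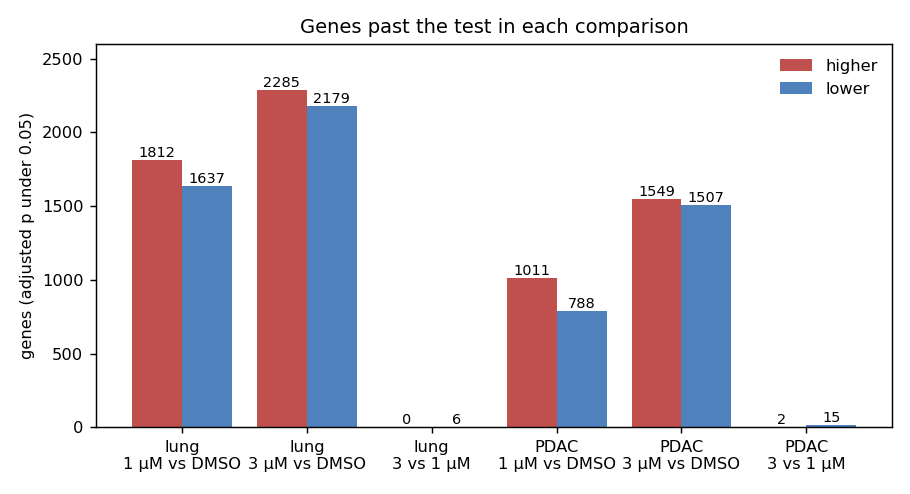
Bars give the number of genes past the edgeR quasi-likelihood test (adjusted p under 0.05, vertical axis) in each comparison within a line, with genes higher at the first-named dose in red and lower in blue. Against DMSO the counts ran from 788 to 2285 per direction, and between 3 and 1 µM from 0 to 15.

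Whether 3 µM changed expression beyond 1 µM was tested directly. In lung CAFs 6 genes differed between the doses by edgeR, of which 0 were higher and 6 lower at 3 µM. DESeq2 called 37 genes and limma-voom 1, both with 0 higher, and 712 genes had an unadjusted edgeR p under 0.05. In PDAC CAFs 17 genes differed by edgeR, 2 higher and 15 lower at 3 µM, against 164 by DESeq2, 29 by limma-voom and 2280 at an unadjusted edgeR p under 0.05. The direction of the PDAC calls depended on the fit as well: 11.8% were higher at 3 µM by edgeR and 36.0% by DESeq2. Without PDAC replicate 2 at 3 µM and lung DMSO replicate 3, 165 genes differed and 64.8% were higher. With only that PDAC replicate 2 left out, 18 genes differed and 22.2% were higher, so the rise to 165 does not come from that library alone. Both counts depended on single libraries. The PDAC count was 1227 without replicate 3 at 3 µM, 7 without replicate 1 at 3 µM, and 7 and 2 without replicates 1 and 2 at 1 µM. The lung count was 24 without replicate 1 at 3 µM, 3 without replicate 3, and 0 by edgeR without replicate 2, where 566 genes had an unadjusted p under 0.05. It was 2, 2 and 1 without replicates 1, 2 and 3 at 1 µM.

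The calls at the 2 doses were then compared. In lung CAFs 3122 genes changed the same way at 1 and 3 µM, which was 90.5% of those called at 1 µM. Independent lists of these sizes would share 426 in the same direction, if each gene were equally likely to be called. Abundant genes were called more often, so such numbers may be too low. In PDAC CAFs 1448 genes changed the same way, 80.5% of those called at 1 µM, against 152 for independent lists. This PDAC count was 944 with the line fitted alone, 2175 without PDAC replicate 2 at 3 µM and lung DMSO replicate 3, and 2545 with the axis covariate, under which the lung count was 4774. By edgeR, DESeq2 and limma-voom alike, 0 genes were called in opposite directions at the 2 doses in either line. At an unadjusted p under 0.05, edgeR had 0 such genes in lung and 2 in PDAC CAFs. Both doses were compared with the same DMSO libraries, so chance values are shared. In 10 simulations of unchanged groups against shared controls, 0 genes overlapped in either line by edgeR. No gene was changed in these simulations, so few could be called, and the 0 cannot gauge what shared controls add to the overlap of called genes. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.793 in lung and 0.748 in PDAC CAFs, against 0.508 and 0.518 in the simulations. The covariance was 0.272 in lung CAFs against 0.0482 simulated, a difference of 0.224, and 0.179 in PDAC CAFs against 0.0437, a difference of 0.136. With 3 DMSO libraries the controls could not be split, so part of the excess overlap may come from them.

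The response score set the doses on 1 scale with genes chosen in the other line. Over the 3056 genes called in PDAC CAFs at 3 µM, lung libraries scored 0.233 ± 0.00808 at 1 µM and 0.270 ± 0.0120 at 3 µM, with an SD of 0.0205 in DMSO (mean log2 change, SD, n = 3). The ratio of the 3 µM score to the 1 µM score was 1.16, and 1.13 to 1.18 with any single treated library left out. The DMSO libraries, which set the 0 of the score, were not varied in this range or in that for PDAC CAFs. Over the 4464 genes called in lung CAFs at 3 µM, PDAC libraries scored 0.135 ± 0.0238 at 1 µM and 0.191 ± 0.0386 at 3 µM, with an SD of 0.0277 in DMSO and a ratio of 1.42 (1.30 to 1.58). The difference between the doses was 0.0368 (SE 0.00834) in lung and 0.0566 (SE 0.0262) in PDAC CAFs. Two-sided exact permutation tests of 3 against 1 µM gave p = 0.1 in lung and p = 0.2 in PDAC CAFs. With genes called in the other line fitted alone, the difference was 0.0510 (SE 0.0117) in lung and 0.0381 (SE 0.0383) in PDAC CAFs, with exact permutation p = 0.1 and p = 0.5. The smallest p that 3 libraries against 3 can give is 0.1, so this comparison could not reach 0.05.

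**Figure D2:**
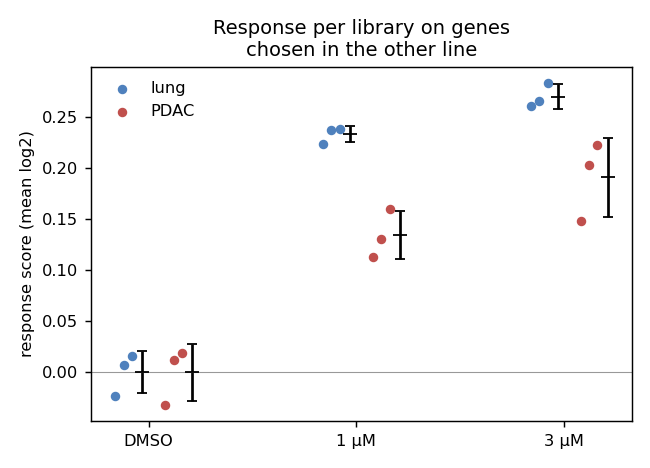
Points give the response score of each library (mean signed log2 change from DMSO, vertical axis) by treatment, in blue for lung and red for PDAC CAFs, with the group mean and SD in black. Each line was scored on the genes called at 3 µM in the other line, and the treated libraries lie between 0.113 and 0.284.

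The next comparison asked which genes changed in both lines, whose fold changes share no libraries, although the dispersions behind the calls were estimated over all 18. At 3 µM, 610 genes rose and 554 fell in both lines, 1164 in all, against 378 for independent lists of these sizes. Another 252 genes were called in opposite directions, against 377 for independent lists. Of these, 118 were higher in lung and lower in PDAC CAFs, and 134 the reverse. At 1 µM, 353 genes rose and 319 fell in both lines, 672 in all, against 173 for independent lists, and 141 were called in opposite directions, against 171. The numbers for independent lists take each gene as equally likely to be called. Abundant genes were called more often in both lines, so these numbers may be too low. With each line fitted alone, 939 genes changed the same way at 3 µM and 497 at 1 µM. The 1 µM count of 672 was 1049 without PDAC replicate 2 at 3 µM and lung DMSO replicate 3, and with the axis covariate the counts were 1872 at 3 µM and 1260 at 1 µM. The log2 fold changes of the lines correlated across all tested genes with r = 0.254 (Spearman 0.222) at 3 µM and r = 0.213 (Spearman 0.195) at 1 µM. Genes are not independent replicates, so no p-value was attached.

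**Figure D3:**
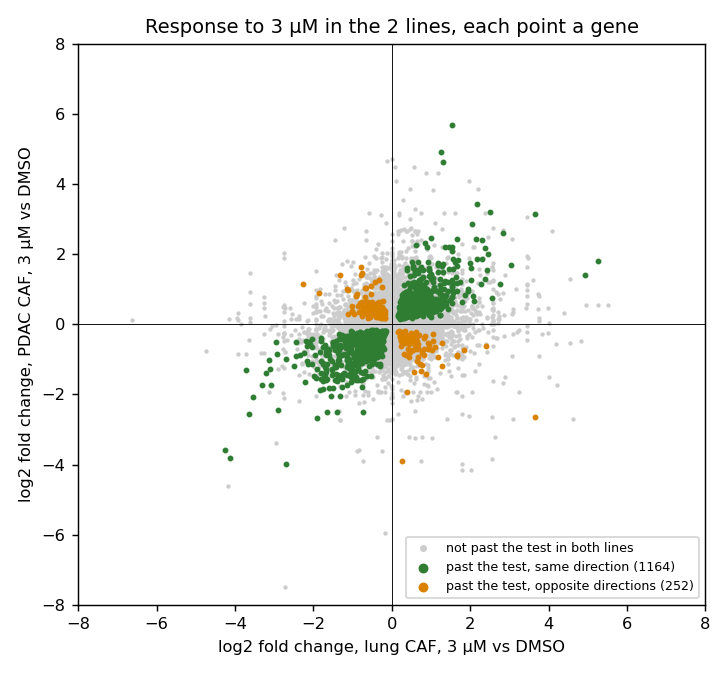
Each point is a tested gene, placed by its log2 fold change at 3 µM against DMSO in lung CAFs (horizontal) and PDAC CAFs (vertical). Green points mark the 1164 genes past the test in the same direction in both lines, orange points the 252 past it in opposite directions, and grey points all others.

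The genes that fell furthest in both lines, by the rule used here, were rows 10784 and 14956 of the count table. Row 10784 stood at 12.8 ± 1.92 CPM in lung DMSO libraries, 1.57 ± 0.338 at 1 µM and 0.658 ± 0.161 at 3 µM (SD, n = 3), with raw counts of 361 to 588 in DMSO and 18 to 37 at 3 µM. Its fall at 3 µM was 19.1-fold in lung CAFs (log2 fold change -4.26, SE 0.18, edgeR adjusted p = 6.97e-12) and 11.98-fold in PDAC CAFs (-3.58, SE 0.19, edgeR adjusted p = 3.23e-10). It was 2.78-fold lower at 3 than at 1 µM in PDAC CAFs (edgeR adjusted p = 0.00578; 0.0601 without replicate 2 at 1 µM). In lung CAFs it was 2.37-fold lower at 3 than at 1 µM (edgeR adjusted p = 0.0426), a call lost in 8 of 19 alternatives. Without a single library the lung adjusted p by edgeR was 0.234 and 0.440 (replicates 2 and 3 at 1 µM left out) and 0.503 and 0.182 (replicates 2 and 3 at 3 µM left out). Row 14956 fell from 77.6 ± 3.02 to 6.18 ± 2.43 CPM in lung CAFs, 12.4-fold (edgeR adjusted p = 2.86e-11), and from 222.7 ± 6.55 to 38.0 ± 5.58 CPM in PDAC CAFs, 5.86-fold (edgeR adjusted p = 1.40e-09), at 3 µM. The difference between the lines in this fall passed the test (edgeR adjusted p = 0.00314). Row 14956 was 2.12-fold lower at 3 than at 1 µM in PDAC CAFs (edgeR adjusted p = 0.00578; 0.0517 without replicate 2 at 1 µM) and 1.72-fold lower in lung CAFs, where it did not pass the test (edgeR adjusted p = 0.280). For row 10784 the lines differed at 1 µM (edgeR adjusted p = 0.0176), where the fall was 8.06-fold in lung and 4.31-fold in PDAC CAFs, and did not pass the test at 3 µM (edgeR adjusted p = 0.136). The call at 1 µM was lost without lung DMSO replicate 3 (0.0517), lung replicate 1 at 1 µM (0.0562) or PDAC replicate 2 at 1 µM (0.0624).

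The genes that rose furthest in both lines were rows 12196 and 8466. Row 12196 rose from 1.94 ± 0.173 to 8.77 ± 1.47 CPM in lung CAFs, 4.49-fold (edgeR adjusted p = 7.12e-09), and from 8.96 ± 1.504 to 32.4 ± 3.40 CPM in PDAC CAFs, 3.61-fold (edgeR adjusted p = 1.12e-08), at 3 µM. Its level at 1 µM was 9.82 ± 0.902 CPM in lung and 33.4 ± 4.05 CPM in PDAC CAFs. Row 8466 rose from 24.1 ± 0.520 to 71.7 ± 1.27 CPM in lung CAFs, 2.98-fold (edgeR adjusted p = 3.83e-11), and from 8.45 ± 0.561 to 31.0 ± 3.45 CPM in PDAC CAFs, 3.66-fold (edgeR adjusted p = 6.48e-11). Neither row passed the test of 3 against 1 µM in either line, nor the test of a difference between the lines at either dose.

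**Figure D4:**
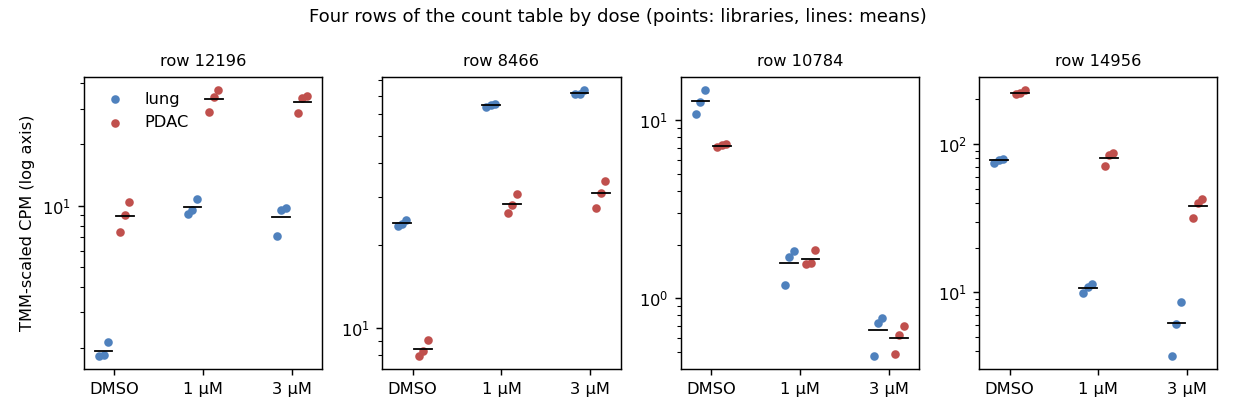
Points give TMM-scaled CPM per library on log axes for rows 12196, 8466, 10784 and 14956, by treatment, with lung CAFs in blue and PDAC CAFs in red and group means as black lines. In all 4 panels the treated libraries of a line do not overlap its DMSO libraries.

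Whether the lines responded differently was tested by the interaction of line and dose. At 3 µM, 2374 genes responded differently by edgeR, 1239 with a more positive and 1135 with a more negative change in PDAC than in lung CAFs. The share with a more positive change was 52.2%, and it was 61.1% with upper-quartile scaling, 45.0% without a filter and 44.8% with the axis covariate, so neither direction prevailed. At 1 µM, 1639 genes responded differently, 859 more positive and 780 more negative. Of the 3048 genes called in lung but not in PDAC CAFs at 3 µM, 1144 (37.5%) passed this test, and of the 1640 called in PDAC but not in lung CAFs, 605 (36.9%) did. The others were not shown to differ between the lines. Among the 1164 genes changed the same way in both lines at 3 µM, 208 (17.9%) differed in the size of the change. The 3 µM count was 3874 without PDAC replicate 3 at 3 µM, with 46.8% more positive.

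The lines were also compared in DMSO. There 10736 of the 18072 genes (59.4%) differed by edgeR, 5542 higher in PDAC and 5194 higher in lung CAFs, with 4510 differing by at least 2-fold. With 1 line per tumour type, this compares these lines and not the tumour types.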

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

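Thinning to equal depth, the test of low expression and the choice of PDAC replicate 2 as the library to leave out were chosen only after the result was seen, although the outcomes expected of them were written down before they were run. The lines differed in their response to the inhibitor in 1639 genes at 1 µM and 2374 genes at 3 µM by the interaction test, a difference between the lines under the same contrast.

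At 3 µM, the values argue against 4 technical explanations as the source of most of the 2374 genes. After thinning all libraries to the smallest total, 2317 genes passed, and under the scaling that called fewer (RLE) the count was 2399. Of the genes called, 8.72% had a mean under 1 CPM in a line, against 29.9% of all tested genes, which argues against expression in a single line as the source of most calls. Without PDAC replicate 2 at 3 µM the count was 2588, and without replicate 3 it was 3874. A higher count does not show that the same genes passed. Of the 2374 genes, 2096 were called again in the same direction without replicate 2, and 2276 without replicate 3. Most calls thus did not rest on either library, although the number called depended on single libraries. A difference in batch or culture and the difference between the tumour types stay open and untested, because each type is 1 line and the labels give no batch. A bias by a property of the genes, raised below for PDAC replicate 2 at 3 µM, stays open too. The checks above were not built to detect it, and the axis covariate was centred within groups, so it could not remove a shift between groups.

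Other splits of the libraries within each line cannot decide whether chance gave these counts. At 3 µM, 3 of 40 splits called as many genes as the real 2374, the real one included, and the highest of the others called 4520. At 1 µM, 2 of 40 did, with 1639 genes in the real split and 3196 in the highest other. The others as large kept the true treatment groups in at least 1 line: those with 4520 and 3196 genes exchanged treated and control labels in 1 line, and that with 2436 genes at 3 µM kept the lung groups and mixed the PDAC groups. A split that keeps the groups of a line keeps its response, so it calls genes whether or not the lines differ. In the 33 splits that mixed the treatments in both lines, edgeR called 0 genes at either dose, but these splits hide the response of both lines.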

How the results depend on the processing

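The alternatives without both PDAC replicate 2 at 3 µM and lung DMSO replicate 3, with the axis covariate, with thinned counts and with recovered reads were chosen after seeing the data. Of 179 recomputed counts other than those leaving out a single library, 138 lay within 1.5 times the main count. For the 4 genes given by row number, 419 of 432 repeats of their calls kept the direction and the side of the threshold, and the other 13 kept the direction but missed the threshold. Those were calls between the doses for rows 10784 and 14956 and the line difference of row 10784 at 1 µM, and the cause was not tested. The totals of 179 and 432 include the repeats on the recovered reads, which are the same counts and so could not disagree. DESeq2 gave no adjusted p for row 10784 between the doses in PDAC CAFs.

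Asking for a log2 fold change of at least 1 left 581 and 793 genes in lung CAFs at 1 and 3 µM, 346 and 514 in PDAC CAFs, 1 and 3 between the doses in lung and PDAC CAFs, and 360 and 480 with a different response at 1 and 3 µM. It left 4510 between the lines in DMSO, 82 and 146 changed the same way in both lines, and 463 and 266 shared by the doses in lung and PDAC CAFs. Fitting each line alone gave 1102 and 1986 genes in PDAC CAFs at 1 and 3 µM, 4 between the doses and 944 shared by the doses, but 4756 and 5798 in lung CAFs, so the gap between the lines widened. The counts between 3 and 1 µM were 59 in lung and 538 in PDAC CAFs without a filter, 37 and 164 with DESeq2, 1 and 29 with limma-voom, and 3 in lung CAFs with the strict filter. The cause was not tested.

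With the replicate number as a block the lung count between doses was 11, and every other count stayed within 1.5 times the main one (4730 genes in lung and 3411 in PDAC CAFs at 3 µM). Deviations from group means of same-numbered libraries correlated at -0.0144 to 0.0367 in lung and -0.0293 to 0.0850 in PDAC CAFs over 5000 genes. Each library was also compared with the 3 libraries of another group of its line. In 5 (lung) and 4 (PDAC) of 9 such comparisons the highest correlation was with the same number. The numbers were not taken to pair the libraries.

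Leaving out 1 library at a time, which lowers the number of samples, gave 2421 to 3079 genes in lung CAFs at 1 µM, 3206 to 3996 at 3 µM, 1238 to 1367 in PDAC CAFs at 1 µM and 2126 to 4276 at 3 µM. Between the doses it gave 0 to 24 in lung and 2 to 1227 in PDAC CAFs. A different response was called in 1136 to 1530 genes at 1 µM and 1718 to 3874 at 3 µM, and 10017 to 10285 differed between the lines in DMSO. Genes changed the same way in both lines numbered 485 to 622 at 1 µM and 873 to 1436 at 3 µM, and those shared by the doses 2202 to 2778 in lung and 1030 to 1954 in PDAC CAFs.

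Without PDAC replicate 2 at 3 µM and lung DMSO replicate 3 there were 3088 genes in PDAC CAFs at 1 µM, 44 and 165 between the doses in lung and PDAC CAFs, 1049 changed the same way in both lines at 1 µM, and 2175 shared by the doses in PDAC CAFs. With only that PDAC replicate 2 left out, the PDAC counts were 18 between the doses and 1954 shared by them. With the axis of differences within groups as a covariate, 5353 genes were called in lung CAFs at 1 µM, 3244 and 5193 in PDAC CAFs at 1 and 3 µM, 55 and 1709 between the doses in lung and PDAC CAFs, and 3456 and 4813 with a different response. That fit gave 1260 and 1872 genes changed the same way in both lines, and 4774 and 2545 shared by the doses in lung and PDAC CAFs. The axis was built from genes that were then tested, so its counts are optimistic. RLE and upper-quartile scaling moved the median gene to at most 0.0548 on the log2 scale. Thinning changed no count by over 1.5 times. The recovered reads gave every main count again, which was fixed in advance because they are the same counts in the same rows. The planned list tests and checks by gene length or GC content were not run, because rows carry no identifiers.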

Other observations

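The tests by response score, on the distance between the lines, on abundance, on PDAC replicate 2 and with the axis covariate were chosen only after the result was seen. Genes called at 3 µM were more frequent among abundant genes in PDAC CAFs too. They made up 6.06% of the 4518 least abundant genes and 27.5% of the 4518 most abundant. Since smaller changes can pass the test at higher counts, this does not show that abundant genes responded more often.

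PDAC replicate 2 at 3 µM stood apart unevenly: of its 1254 genes at least 1.5-fold off, 1213 were lower and 41 higher. Whether another strength of response to the inhibitor was the source stays open. In a fit without the 3 µM libraries, 4.94% of these genes changed at least 1.5-fold at 1 µM, with a median of 1.09-fold. That share cannot decide, because only 3.07% of all genes of at least 5 CPM changed that much, too few to make up most of the 1254. Across the genes of at least 5 CPM the deviation correlated at 0.0342 with the log2 fold change at 1 µM, so a deviation in proportion to that response was not seen. The response score of replicate 2 was 0.148, below the 0.203 and 0.222 of replicates 1 and 3 at 3 µM. That score of a single library does not decide the question either. Low depth is argued against by a deviation of 0.352 log2 units among the most abundant genes, where no library outside its group exceeded 0.193, and admixture of the lung line by a median of 0.0612% of the lung level over 10 genes nearly absent from the other PDAC libraries. A bias by a property of the genes may be a source: the deviation correlated across genes at -0.441 with that of lung replicate 2 at 1 µM, at 0.434 with PDAC replicate 2 at 1 µM and at 0.393 with lung DMSO replicate 3. Which property it would be stays open without gene identities, and a difference between cultures was not tested.

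The small difference between 1 and 3 µM raises the hypothesis that the response was complete at 1 µM. In lung CAFs this is argued against by the response score, which was 0.0368 higher at 3 µM (SE 0.00834) with no overlap of the libraries, although 3 libraries against 3 cannot give an exact p under 0.1. In PDAC CAFs the score was 0.0566 higher (SE 0.0262), or 0.0381 (SE 0.0383) with genes called in the lung line fitted alone. The libraries of the doses overlapped. On the first score only replicate 2 at 3 µM (0.148) fell within the range at 1 µM, whose highest library scored 0.160. Replicates 1 and 3 at 3 µM scored 0.203 and 0.222. A response complete on average cannot be told apart from a further rise in PDAC CAFs, because the 3 µM libraries spread widely. Of the 4 genes given by row number, which were chosen for their change at 3 µM and so decide nothing on the response as a whole, rows 10784 and 14956 were 2.78-fold and 2.12-fold lower at 3 than at 1 µM in PDAC CAFs (edgeR adjusted p = 0.00578 for both, 0.0601 and 0.0517 without replicate 2 at 1 µM), and rows 12196 and 8466 did not pass the test (0.922 and 0.523). The 17 genes called between the doses in PDAC CAFs may be few because of that spread, which stays open. With the axis covariate 1709 were called, a count that is itself optimistic, and 1227 without replicate 3 at 3 µM. Without replicate 2 at 3 µM, the library furthest off, the count was 18, which goes the other way. The fit with 1227 genes kept replicate 2, and 19.5% of its calls were higher at 3 µM. Of the 1254 genes off in replicate 2, 1213 were lower. The 1227 calls thus cannot be told apart from the deviation of that library.

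A further hypothesis was that the inhibitor brought the lines closer together, and the distances argue against it. The root mean square log2 difference between a lung and a PDAC library was 1.46 in DMSO (range 1.45 to 1.48 over 9 pairs) and 1.51 at 3 µM (1.49 to 1.53), a ratio of 1.03.

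Libraries were also regrouped for the other comparisons. A chance assignment of libraries without any response is argued against for the genes changed the same way in both lines, where 1 of 40 splits, the real one, reached 1164 at 3 µM (highest other 252) and 672 at 1 µM (highest other 141). The highest others exchanged treated and control labels in 1 line, and the splits do not test whether the overlap of the lines is larger than that of independent lists. For the genes shared by the doses, 1 of 40 splits, the real one, reached 3122 in lung and 1448 in PDAC CAFs, with 0 by edgeR as the highest other. A split that mixes DMSO with treated libraries hides the response. These splits thus argue only against a chance assignment without any response, and do not test how far the doses share genes. Nor do they test the part that may come from the shared DMSO libraries. Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. The real counts of 3449 and 4464 in lung and 1799 and 3056 in PDAC CAFs at 1 and 3 µM, 6 between the doses in lung CAFs and 10736 between the lines in DMSO each stood against 0 by edgeR as the highest other. In PDAC CAFs 2 of 10 splits called at least the 17 genes found between the doses, and the highest other called 105. That split set replicates 1 and 3 at 1 µM with replicate 3 at 3 µM against the rest, and its count, several times the real one, points to a structure of the libraries other than dose.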
